A study of Homo sapiens with 4 samples.

How the data were processed

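RNA from SW480 cells, a colorectal adenocarcinoma cell line, was measured on Affymetrix expression arrays, 1 array per sample. Per the labels' titles, 2 arrays came from cells with a knock-down of the homeobox gene HOXA5 and 2 from cells overexpressing it. That the cells were transduced is taken from the labels and the series' design text, as the titles do not say it. Total RNA was extracted with a commercial kit, its integrity was assessed on a Bioanalyzer and it was labelled with biotin, per the labels' protocols. The replicate numbers were taken from the titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

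The deposited table holds log2 expression values for 54675 probe sets in 4 columns. The authors made them with RMA in the affy package, per the submitters' processing notes; the versions and the annotation used are not given in the sources used here. RMA corrects the background of the probes, makes the distributions of the arrays alike and summarises each probe set on the log2 scale. It gives no detection call, so values near the bottom of the scale could not be marked as background, and a fold from such a value is set by that floor. The near-equal quantiles of the columns (medians 5.77 to 5.81) left no visible difference in scale. The values were used as deposited, with no further scaling in the main analysis. As these are array values with no read counts, the number of arrays limits the precision.

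Of the probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several symbols and 11721 were not listed with a gene in the annotation table of the platform. The symbols of 41037 probe sets matched a current human RefSeq gene table by gene identifier. Control probe sets and probe sets with several or no symbols were left out of the tests by gene. Each of the 19775 genes was represented by its probe set with the highest mean over the 4 arrays, a rule blind to the groups; 10523 genes had more than 1 probe set. No probe set was named HOXA5 in the table used here, so the planned check of the manipulated gene is not reported here; 1 other gene that was to be named was not covered either. Early on, values of probe sets recalled from memory as those of both genes were looked up, and those recalled for HOXA5 were compared between the groups when the labels were weighed. The table does not name them, so no script or result uses them. No coordinates are given because no genome build was named for the values.

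Overexpressing arrays were compared with knock-down arrays with limma (version 3.58.1, R 4.3.3): lmFit with the group as the sole term and eBayes with default settings, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p of 0.05. There was no filter on dim genes and no fold threshold. The fit had 2 residual degrees of freedom per gene and a prior worth 4.17. A value compared by itself in 2 against 2 arrays cannot reach an exact two-sided permutation p below 0.333, so single-gene calls rest on the spread shared across genes. In simulated values for the 19775 genes with the fitted spread, 200 genes were changed. The procedure recovered 22% of the genes changed by 0.5 on the log2 scale and 98% of those changed by 1. It recovered 100% of those changed by 2 or 3, and it called 11 unchanged genes. The simulated spread came from the fitted prior, independent between genes and unrelated to intensity. These rates therefore hold only where the data meet the assumptions of the test. They also depend on how many genes change: 200 were changed in the simulation, whereas 944 passed in the data.

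The design, the alternatives, 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists were tested with camera with the inter-gene correlation preset at 0.01, adjusted over the lists; 905 of their 1002 entries were measured and named in the table used here. Camera with an estimated correlation, camera on ranks and fry were alternatives. fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Named genes were the 12 with the largest positive and the 12 with the largest negative difference among those past the threshold whose groups did not overlap; from each list up to 4 members past the threshold with the largest absolute difference or, where none passed, the 2 with the highest mean level; and LGR5, ASCL2, AXIN2, MYC, CD44, KRT20, CDX2, VIL1 and MUC2 whatever their result. Further list members that are mentioned to complete a count were chosen after their values were seen.

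The other alternatives were an intensity trend with robust moderation, the replicate number as a block, centring of the arrays, a second quantile normalization, a filter on dim genes, the mean of a gene's probe sets, a test per probe set, other thresholds and leaving out each array in turn. Leaving out 1 array leaves 1 residual degree of freedom, and the lone array of a group is then assumed to vary like the other group. The RNA integrity of the arrays was checked from the 3' and 5' control probe sets of ACTB and GAPDH. Scanner files were not used here, so scan dates could not be checked as batches.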

Results

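Gene expression was profiled in SW480 cells, an established colorectal cancer line that carries a truncated APC and therefore has an active Wnt pathway. The cells had been transduced to change the level of HOXA5, a homeobox transcription factor. There were 2 arrays labelled HOXA5 knock-down and 2 labelled HOXA5 overexpressing, and no untransduced or vector control. Every difference below is therefore overexpressing minus knock-down. Such a difference cannot be assigned to either manipulation alone, or told apart from other differences between the transduced cell populations. Values were RMA log2 expression, with array medians between 5.77 and 5.81. Over all probe sets, arrays of the same group correlated at 0.997 in both groups, and arrays of different groups at 0.991 to 0.993. The SD of the difference between arrays was 0.175 and 0.180 within groups and 0.284 to 0.310 between groups. HOXA5 itself is not reported, because none of the named probe sets belonged to it, so these results do not show whether the labels hold for the manipulated gene. The number of arrays limits the precision, and the labels do not say whether replicates came from separate cultures.

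The first comparison asked which genes differed between overexpressing and knock-down cells. The largest differences were rises in the overexpressing arrays, led by APCDD1 and DKK4, which encode inhibitors of Wnt signalling that are themselves Wnt-induced. The title of the series has HOXA5 inhibiting Wnt signalling, whereas these and other Wnt target genes were higher in the arrays labelled overexpressing. APCDD1 rose 71.6-fold on the brighter of its 2 probe sets, from 4.21 ± 0.58 to 10.38 ± 0.12 (log2, SD, n = 2 per group). DKK4 rose 59.3-fold, from 5.45 ± 0.02 to 11.34 ± 0.11. EPCAM, the epithelial cell adhesion molecule, rose 33.0-fold from 3.73 ± 0.11 to 8.78 ± 0.04. In the other direction, NID2, a basement membrane nidogen, fell by 3.37 on the log2 scale, from 10.06 ± 0.003 to 6.69 ± 0.11.

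Of 19775 genes tested, 944 (4.77%) passed an adjusted p of 0.05 in limma, 542 higher and 402 lower in the overexpressing arrays. Large changes were mostly rises: 203 genes were higher and 43 lower by at least 1 on the log2 scale, and 56 higher and 2 lower by at least 2. The 12 largest rises included, besides those above, ID2, an inhibitor of basic helix-loop-helix factors (log2 difference 5.60 ± 0.15, SE, adjusted p = 2.33e-05), the keratins KRT23 (4.62 ± 0.12) and KRT19 (4.38 ± 0.08), and FOXQ1, a forkhead transcription factor (4.24 ± 0.15). The others were QPCT, a glutaminyl cyclase (4.67), EDIL3, a secreted integrin ligand (4.23), SERPINE2, a serine protease inhibitor (4.19), CCND2, encoding cyclin D2 (3.85), and MPZL2, an adhesion molecule (3.80). All of these 12 but SERPINE2 had a knock-down mean below the median of every array, from 3.62 (QPCT) to 5.45 (DKK4 and MPZL2). Weaker probe sets gave 1.92 for APCDD1 (6.16 on its brightest), 3.56 for ID2, 1.68 for SERPINE2 and 1.96 and 4.10 for MPZL2. They gave 0.04 for KRT19, 0.37 and 0.10 for EDIL3 and 1.26, 0.29 and 0.16 for CCND2. RMA values carry no detection call, so these folds are as measured from the low end of the scale.

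The 12 largest falls were smaller. After NID2 came GLIS3, a zinc finger transcription factor (-2.23 ± 0.13, SE, adjusted p = 4.36e-04), NIBAN1 (-1.92) and FAR2, a fatty acyl-CoA reductase (-1.87). They were followed by FAM13C (-1.71), RAP1A, a Ras-like GTPase (-1.69), FAM124A (-1.66), FUT3, the Lewis fucosyltransferase (-1.62), SEMA3C, a secreted semaphorin (-1.61), NPR3, the natriuretic peptide clearance receptor (-1.61), ZNF804A (-1.57) and ANKRD29 (-1.56). The brightest probe set of RAP1A fell from 12.54 ± 0.04 to 10.85 ± 0.10 and another differed by -1.82, but the remaining 2 of its 4 probe sets, 1 of them also bright, differed by -0.03 and -0.05. A weaker probe set each of SEMA3C (0.08), FAR2 (0.01), FAM13C (-0.07) and FAM124A (-0.07) showed no such difference. Other weaker probe sets differed by -1.71 for FAR2 and by -0.84, -0.28 and -0.23 for FAM124A. Leaving out any one array left 172 to 237 genes past the threshold; of these 24 genes, FAM13C then missed it without either knock-down array and ANKRD29 without overexpressing replicate 1 (highest adjusted p 0.083 and 0.061). The split of calls was 57.4% higher, but 48.8% with an intensity trend in the variances and 40.5% among genes above the median level.

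**Figure D1:**
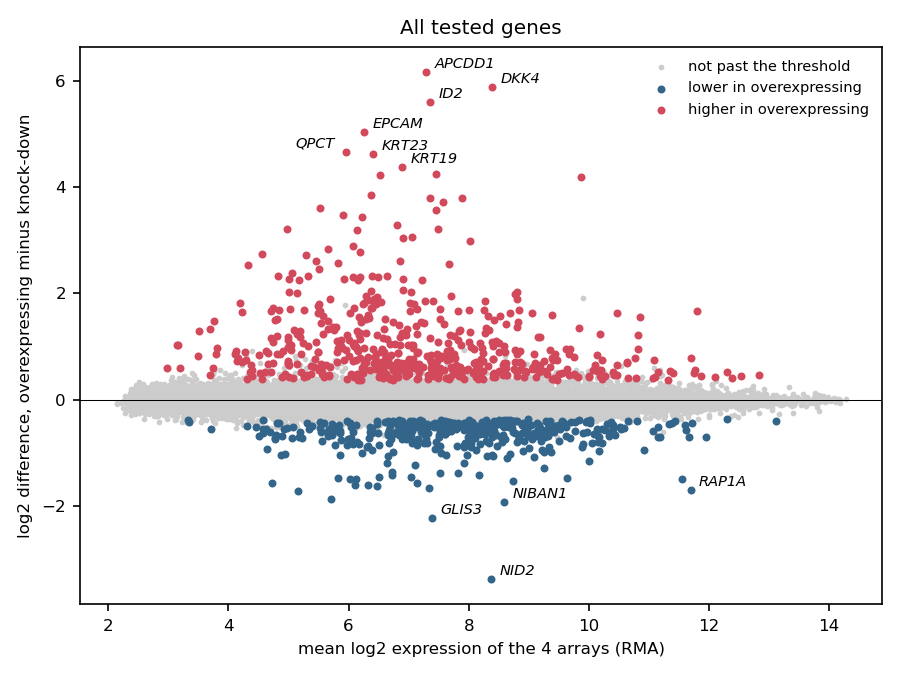
Log2 difference (overexpressing minus knock-down, n = 2 arrays each) against mean log2 expression for the 19775 genes; red and blue points are the 542 higher and 402 lower genes past an adjusted p of 0.05. The points beyond 2 on the log2 scale are 56 higher and 2 lower genes.

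Wnt target genes and intestinal stem cell markers were compared because the series concerns Wnt signalling and stem cell traits. Of 35 measured Wnt target genes, 16 rose in the overexpressing arrays, 1 fell and 18 did not pass; adjusted over the list alone, 18 rose and 4 fell. AXIN2, a feedback inhibitor of the pathway, rose 9.27-fold (5.88 ± 0.01 to 9.09 ± 0.29), and SP5, a Wnt-induced transcription factor, rose 4.82-fold (adjusted p = 0.0014). DKK1, CCND1, TRIB2, BMP4, NKD1, NOTUM, ZNRF3, JUN and PLAUR were also among the genes that rose, by at least 0.42 (NOTUM). NRCAM, an adhesion molecule, fell by 0.74. MYC, a classical target in colorectal cancer, was at 11.63 ± 0.02 and 11.64 ± 0.07 (adjusted p = 0.97), and CD44 at 9.49 ± 0.03 and 9.25 ± 0.04 (adjusted p = 0.16). Of the 13 probe sets of CD44, 11 were below 0 and 7 of these had an unadjusted p under 0.05, down to -0.38. As a list, Wnt target genes stood higher in the overexpressing arrays (camera adjusted p = 8.56e-11; adjusted p = 0.27 with an estimated correlation), with a median difference of 0.30.

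Of 26 measured intestinal stem cell markers, 8 rose, 1 fell and 17 did not pass; adjusted over the list alone, 9 rose and 2 fell. ASCL2, a transcription factor of crypt base stem cells, rose 3.53-fold (adjusted p = 2.01e-04), SOX9 rose 3.64-fold (adjusted p = 2.29e-04) and RNF43, a ubiquitin ligase acting on Wnt receptors, rose 2.52-fold (adjusted p = 0.0036). DCLK1, CD24, CDK6, AXIN2 and ZNRF3 completed the rises, and ALCAM fell by 0.56. LGR5, the receptor that marks crypt base stem cells, was low in both groups, at 4.12 ± 0.09 and 4.27 ± 0.03 (adjusted p = 0.41). The list stood higher as a whole (camera adjusted p = 1.25e-05; adjusted p = 0.27 with an estimated correlation), with a median difference of 0.06. The lists share 8 measured genes. Among the 18 markers not shared, 3 rose and 1 fell. AXIN2 has 4 probe sets, of which the brightest gave 3.21, another 0.49 and the others -0.04 and -0.11. The calls on SP5 and RNF43 were lost without either overexpressing array (highest adjusted p 0.068 and 0.094), with differences of at least 1.99 and 1.16.

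**Figure D2:**
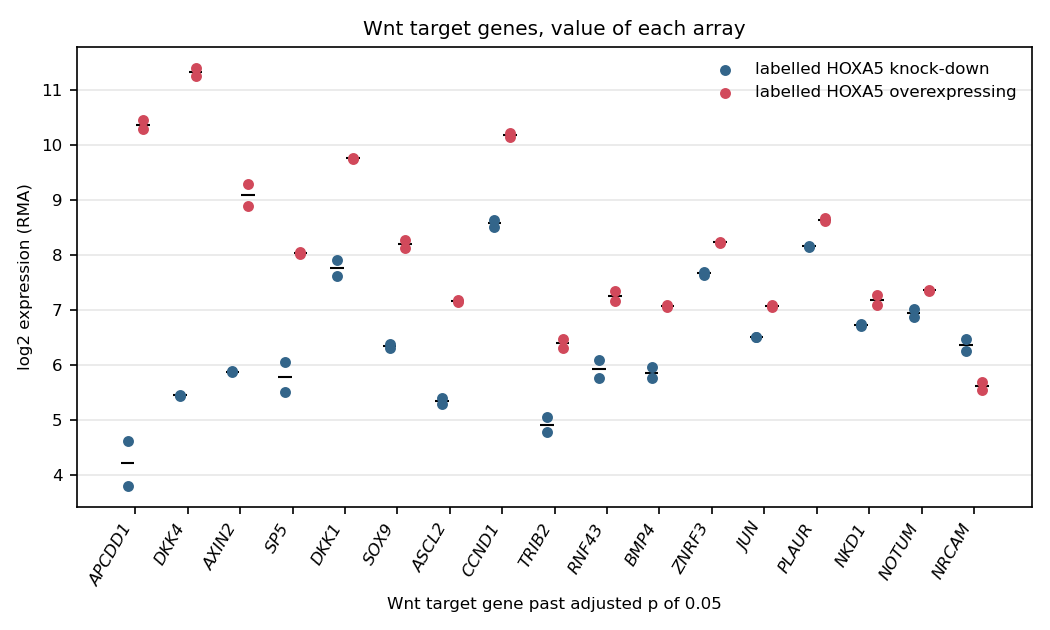
Log2 expression of the 17 Wnt target genes past the threshold in each of the 4 arrays (points) with the group mean (black line), ordered by difference. In 16 of them both overexpressing arrays lie above both knock-down arrays, and NRCAM lies the other way. The groups did not overlap in any of the 944 genes past the threshold, nor in 9277 of the 19775 tested, so this separation adds no support.

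Ligands, receptors and cascade members of the Wnt pathway differed little: of 57, 3 rose and none fell (6 and 0 adjusted over the list alone). The genes that rose were WNT6 (0.83, but 0.05 on a probe set nearly as bright), RSPO3 (0.69) and FZD10 (0.58), and the list did not stand apart (camera adjusted p = 0.54). Of the 38 other HOX genes, 28 were measured here, of which 4 rose and none fell (5 and 0 adjusted over the list alone), namely HOXB8 (2.32 ± 0.29, SE, adjusted p = 0.0094; 0.14 on its weaker probe set), HOXB2 (0.80), HOXB6 (0.44) and HOXB3 (0.39). The HOX list did not pass (camera adjusted p = 0.11). None of 10 measured TALE homeobox genes, a class that includes partners of HOX proteins, passed in limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05). TGIF1 differed by 0.03 and MEIS2 by -0.06, and the list did not pass (camera adjusted p = 0.66). Of all 19775 genes, 3688 had an unadjusted p under 0.05 in limma. RSPO3, FZD10, HOXB8, HOXB2, HOXB6 and HOXB3 lost the call whichever array was left out, and WNT6 kept it only without knock-down replicate 1. WNT6, HOXB6 and HOXB3 did not pass when all probe sets of a gene were averaged. HOXB3 did not pass with the arrays centred on their medians either. With the replicate number as a block, WNT6 (adjusted p = 0.092), RSPO3 (0.104), HOXB6 (0.068) and HOXB3 (0.082) did not pass.

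Markers of intestinal differentiation mostly did not pass. Of 35 enterocyte genes, 4 rose and none fell (4 and 0 adjusted over the list alone): KRT19, the scaffold gene EPS8L3 (1.06), the sulphate transporter SLC26A2 (0.93) and the intestinal homeobox gene CDX2 (0.51, adjusted p = 0.025). The terminal marker KRT20 was near the bottom of the scale at 2.97 in both groups. VIL1, encoding villin, differed by 0.02 on its brightest probe set (adjusted p = 0.95), whereas the mean of its 4 probe sets passed at 0.45. Of 34 secretory lineage genes, SPINK4, a goblet cell peptide, rose (1.04, adjusted p = 0.0029) and none fell (1 and 0 adjusted over the list alone), and the goblet mucin MUC2 was at 5.19 ± 0.02 and 5.22 ± 0.07. Neither list stood apart (camera adjusted p = 0.16 and 0.82). CDX2 missed the threshold whichever array was left out, and EPS8L3 and SPINK4 missed it without some of the arrays.

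Epithelial adhesion genes were split: of 28, 5 rose and 1 fell (8 and 2 adjusted over the list alone). EPCAM, the epithelial transcription factor KLF5 (1.51), the tight junction gene CLDN4 (1.26) and the desmosomal gene PKP2 (0.79) rose together with OVOL2, and ELF3 fell by 0.69. Of 36 mesenchymal genes, the matrix gene TNC (1.33) and the repressor SNAI2 (1.26) rose and the collagen cross-linking enzyme gene LOXL2 fell by 0.99 (2 and 1 adjusted over the list alone). The lists did not pass (camera adjusted p = 0.13 and 0.11). TNC was at 3.03 ± 0.33 in the knock-down arrays, near the bottom of the scale, and at 4.36 ± 0.08 in the overexpressing arrays. A single probe set carried TNC and CLDN4 (the other of CLDN4, nearly as bright, differed by 0.003), and LOXL2 did not pass as the mean of its 4 probe sets. EPCAM stayed past the threshold whichever array was left out, whereas KLF5, PKP2 and LOXL2 then missed it in every case. CLDN4, TNC and SNAI2 missed it without some of the arrays.

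Next came the lists of TGF-beta and BMP, inflammatory and immediate-early genes. Of 38 TGF-beta and BMP pathway genes, 6 rose and 1 fell (10 and 3 adjusted over the list alone). ID2 led, followed by the ligand BMP2 (0.78 ± 0.08, SE), the pseudoreceptor BAMBI (0.75), the receptor TGFBR2 (0.61), ID1 and SMAD2, while ID3 fell by 0.44. The list passed (camera adjusted p = 0.0042; adjusted p = 0.50 with an estimated correlation). Of 31 genes of the NF-kB and inflammation list, 8 rose and none fell (13 and 1 adjusted over the list alone). IER3 (1.57), the cyclooxygenase gene PTGS2 (1.54), the chemokine gene CCL20 (1.17) and the cytokine gene IL6 (1.02) led, and CXCL1, CXCL2, NFKBIZ and LCN2 also rose (camera adjusted p = 1.25e-05; adjusted p = 0.27 with an estimated correlation). Of 26 immediate-early genes, 5 rose and none fell (7 and 0 adjusted over the list alone): DUSP6, a phosphatase of ERK (1.81, and 4.38 and 3.29 on its weaker probe sets), MAFF (1.58), CCN2 (1.19), EGR1 (0.69) and EGR3 (camera adjusted p = 4.17e-05; adjusted p = 0.50 with an estimated correlation). BMP2, TGFBR2 and EGR1 lost the call whichever array was left out, and BAMBI, CCL20 and DUSP6 lost it without some of the arrays. TGFBR2 also lost it as a mean of its probe sets.

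Notch, Hedgehog and retinoid genes moved in both directions. Of 34 Notch pathway genes, HES1 (1.09, adjusted p = 7.77e-04) and DTX4 (0.77) rose and DTX3L fell by 0.48 (2 and 2 adjusted over the list alone). Of 16 Hedgehog pathway genes, the receptor gene PTCH1 (1.23), GLI3 (0.61) and GLI2 (0.42) rose and the forkhead gene FOXF1 fell by 1.43 (5 and 2 adjusted over the list alone). Of 25 retinoid pathway genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone): TGM2 (1.32) and RARRES2 rose, and DHRS3 (-0.73), the retinoic acid binding protein gene CRABP2 (-0.70) and RARRES1 (-0.60) fell. None of these lists passed (camera adjusted p = 0.86, 0.060 and 0.92). HES1, PTCH1, FOXF1 and TGM2 stayed past the threshold whichever array was left out. DTX4, DTX3L, GLI3, GLI2, DHRS3, CRABP2 and RARRES1 missed it whichever array was left out. PTCH1 and GLI2 did not pass as means of their probe sets, and DTX3L did not after a second quantile normalization.

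Genes of the division cycle showed small differences. None of 38 G2/M genes passed in limma (0 adjusted over the list alone, 8 at an unadjusted p under 0.05), but 32 of the 38 had a difference below 0, with a median of -0.14, and the list stood lower (camera adjusted p = 5.0e-04; adjusted p = 0.50 with an estimated correlation). The abundant members UBE2C and CCNB1 differed by -0.03 and -0.08. None of 37 G1/S genes passed either (0 adjusted over the list alone, 5 at an unadjusted p under 0.05). Their median was 0.0009 (camera adjusted p = 0.70), with TYMS at -0.02 and PCNA at 0.03. The counts at an unadjusted p under 0.05 compare with 3688 of all 19775 genes in limma. Replication-dependent histone genes stood higher: 5 of 11 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 8.39e-09; adjusted p = 0.27 with an estimated correlation). They included H2AC6 (0.76), H2BC5 (0.68), H1-2 (0.57), H2BC12 (0.50) and H2BC9. H2AC6, H2BC5, H1-2 and H2BC12 each missed the threshold whichever array was left out (highest adjusted p 0.25). The 3' minus 5' difference of the ACTB control probe sets was 0.41 and 0.46 in the knock-down arrays and 0.43 and 0.30 in the overexpressing arrays.

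Metabolic and stress lists were mixed. Of 25 genes of cholesterol and fatty acid synthesis, SQLE (-0.60), INSIG1 (-0.49), HMGCS1 (-0.40) and MSMO1 fell and TM7SF2 rose (0.48), or 2 higher and 6 lower adjusted over the list alone. The list stood lower (camera adjusted p = 0.019; adjusted p = 0.61 with an estimated correlation), but not without overexpressing replicate 1 (0.14) or knock-down replicate 2 (0.066), nor with the mean of the probe sets (0.087), where SQLE (adjusted p = 0.18) and INSIG1 (adjusted p = 0.067) did not pass either. Of 23 NRF2 and xenobiotic genes, 4 rose and 3 fell (5 and 8 adjusted over the list alone), including the peroxidase GPX2 (1.46), the aryl hydrocarbon receptor repressor AHRR (1.36), the haem oxygenase gene HMOX1 (-0.97) and GSR (-0.72). Of 31 hypoxia and glycolysis genes, the glucose transporter genes SLC2A3 (1.37) and SLC2A1 (1.07) rose and ADM (-0.97) and ALDOC (-0.72) fell (3 and 4 adjusted over the list alone). Of 33 genes of the unfolded protein response, the cystine transporter gene SLC7A11 (-1.04) and NUPR1 (-1.03) fell and none rose (0 and 2 adjusted over the list alone). Of 36 interferon-stimulated genes, 3 rose and 2 fell (10 and 5 adjusted over the list alone), among them ISG15 (0.65), OASL (0.53), EPSTI1 (0.45) and IFI6 (-0.61). PHLDA3 (0.67) rose in the p53 target list of 23 and BIK (1.25) among 24 apoptosis regulators, and none fell (3 and 0, and 2 and 1, adjusted over the list alone). The camera adjusted p of these last 6 lists were 0.86, 0.86, 0.55, 0.23, 0.11 and 0.55. AHRR stayed past the threshold whichever array was left out. SQLE, INSIG1, HMGCS1, TM7SF2, HMOX1, GSR, ALDOC, ISG15, OASL, EPSTI1, IFI6 and PHLDA3 missed it in every such case. GPX2, SLC2A3, SLC2A1, ADM, SLC7A11, NUPR1 and BIK missed it without some of the arrays.

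Reference lists and markers of other cell types had no gene past the threshold. No gene passed in limma, over all genes or adjusted over the list alone, among 24 housekeeping, 29 ribosomal protein, 27 oxidative phosphorylation, 30 MYC and ribosome biogenesis and 13 heat shock genes, or among 14 fibroblast, 12 endothelial and 16 haematopoietic markers. At an unadjusted p under 0.05 in limma there were 7 among the 165 members, against 3688 among all 19775 genes. The lowest camera adjusted p of these 8 lists was 0.55. GAPDH differed by -0.05 and PPIA by -0.01; RPL37 by -0.07 and RPS6 by -0.03; COX7B by -0.05 and ATP5PB by -0.01; HSPD1 and LDHA by 0.02 each; HSP90AA1 by -0.02 and HSP90AB1 by -0.05. At an unadjusted p under 0.05, a weaker probe set of HSP90AA1 (0.63) and of RPL37 (0.66) was higher and one of RPS6 (-0.58) and of COX7B (-0.33) lower. FBLN1, the brightest fibroblast marker, was at 10.51 ± 0.11 and 10.12 ± 0.11 (adjusted p = 0.086), and passed with an intensity trend or among genes above the median level. COL1A1 differed by 0.15, CDH5 by 0.19, PECAM1 by 0.07, CD79A by 0.13 and CD3E by -0.12. The median and the mean had opposite signs in the Wnt cascade, enterocyte, Notch, NRF2, hypoxia and fibroblast lists, none of which passed. In the hypoxia and NRF2 lists camera's direction was down with a mean above 0, and in the haematopoietic list it was up with a median and a mean below 0. Weaker probe sets had differences of the opposite sign for WNT6, HOXB6, TGM2, PKP2, TNC, TGFBR2, HES1 and GLI2 (-0.13 at most below 0) and for SQLE (0.25), none past an unadjusted p of 0.05. Of 55 named calls with more than 1 probe set, 25 had a probe set that missed an unadjusted p of 0.05. In 13 of them (CLDN4, FAM13C, GLI2, GPX2, HOXB3, HOXB6, HOXB8, KRT19, PKP2, SEMA3C, TGFBR2, TNC and WNT6) the brightest alone passed it in the direction of the call. Of the 92 named genes past the threshold, 92 kept their direction and 36 the threshold whichever array was left out.

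**Figure D3:**
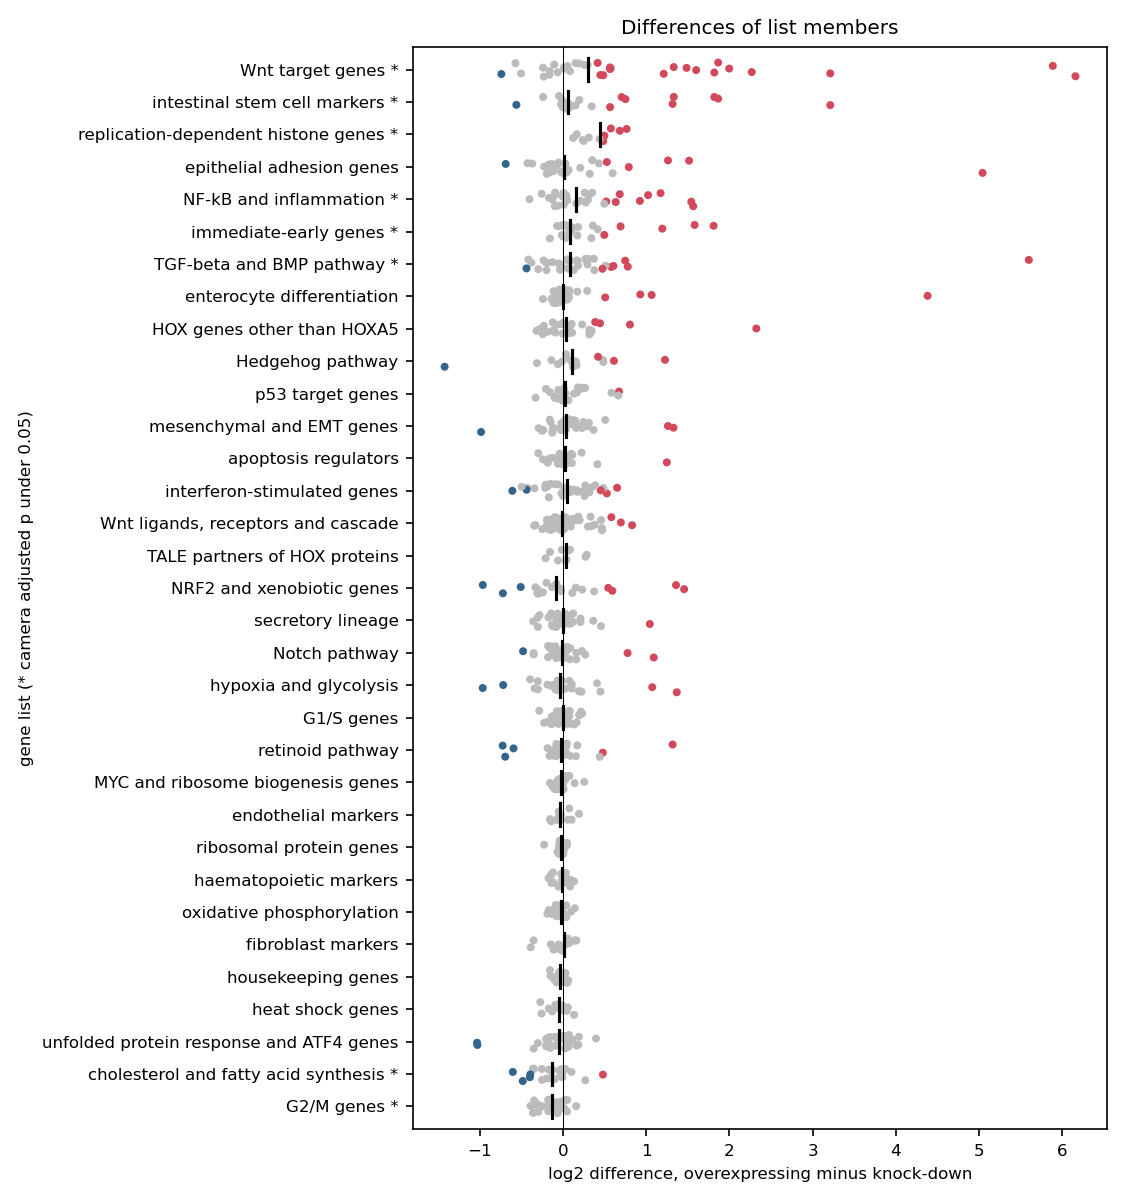
Log2 difference (overexpressing minus knock-down) of every measured member of the 33 gene lists, ordered by list mean; red and blue points passed an adjusted p of 0.05 over all genes, grey points did not, black bars are list medians and asterisks mark camera adjusted p under 0.05. The Wnt target list has 16 red points and 1 blue point, and the G2/M list has grey points alone around a median of -0.14.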

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

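All alternatives were planned. The count of 944 genes became 1822 with an intensity trend and robust moderation, 520 with the replicate block, 1561 at an adjusted p under 0.10 (775 higher and 786 lower), 246 with a log2 difference of at least 1, 203 with treat against 0.5, and 172 to 237 without any one array, where 1 residual degree of freedom is left; the 4 counts were 237 without knock-down replicate 1, 231 without knock-down replicate 2, 172 without overexpressing replicate 1 and 187 without overexpressing replicate 2. The count stayed within 1.5 times (1007 to 1358) with centring, a second quantile normalization, the dim-gene filter, averaged probe sets and the test per probe set. The genes called were not all the same. Of the 944, 933 passed again with centring and 939 with the second normalization. With averaged probe sets 732 did, and with the dim-gene filter, which kept 9887 genes, 599 did. The test per probe set called 1078 of 54613 probe sets, which are not genes. The share of called genes that were higher, 57.4%, was 66.3% with the replicate block, 53.1% with centred arrays, 76.5% to 84.0% without any one array, 48.8% with the intensity trend and 40.5% among genes above the median level; in these last cases most calls were falls, and the cause was not tested. The median difference over all genes was -0.02 in the main analysis and -0.03 after centring. Against 8 lists past the threshold, 7 to 9 lists passed in the other settings, apart from fry with 6 (4 of them among the 8) and camera with an estimated correlation with 0, where the Wnt target and the stem cell lists both had an adjusted p of 0.271; with 2 residual degrees of freedom the estimated correlation has little to rest on. In fry, the G2/M (0.088), TGF-beta and BMP (0.052), immediate-early (0.062) and cholesterol (0.13) lists missed the threshold and the enterocyte (0.017) and HOX (0.014) lists passed. Without knock-down replicate 2, the epithelial and mesenchymal lists (0.034 each) passed, and the HOX list (0.015) did among genes above the median level. Whether same-numbered arrays are paired stays open: the replicate 1 minus replicate 2 differences of the groups correlated at 0.15 (0.23 among genes above the median level), and gene-centred values at -0.738 and -0.747 with the same number against -0.811 with different numbers. The replicate block ended 18 of the 92 named calls (WNT6, RSPO3, CDX2, HOXB6, HOXB3, OASL, EPSTI1, CLDN4, BAMBI, TGFBR2, DTX4, DTX3L, GLI3, GLI2, INSIG1, TM7SF2, HMGCS1 and H2BC12) and no list call, and no named call turned its direction in any alternative. No alternative could be run for HOXA5. Without detection calls, what signal over background limits could not be set.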

Other observations

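Some gene groups outside the fixed lists were described after their values were seen. Genes known from blood cells were picked from those past the threshold, so they test no group: CST7, encoding cystatin F (3.07 ± 0.08 on the log2 scale, SE), PRF1, encoding perforin (2.99 ± 0.11), the tyrosine kinase genes SYK (2.61) and ZAP70 (2.31), LMO2 (1.81), PIK3R5 (1.73) and IL10 (1.69) rose, whereas VAV3 fell by 1.08. None of the 16 haematopoietic markers passed. Of 42 measured keratins, 4 rose (KRT23, KRT19, KRT5 at 3.80 and KRT71 at 0.94) and none fell. Of 16 antigen processing genes, the immunoproteasome genes PSMB8 (-0.81) and PSMB9 (-0.80) fell and none rose; the median was -0.22. Of 13522 probe sets without a single gene symbol, 104 passed an adjusted p of 0.05 in the limma test per probe set.

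Of the tests below, those on the exchange of single arrays and of whole groups, on dividing cells and on RNA integrity were chosen after the result was seen. Wnt target genes were higher in the arrays labelled overexpressing, against the direction named in the series' title. Taking the brightest probe set alone was not needed for the list to stand higher. The list also stood higher with the mean of all probe sets (camera adjusted p = 4.91e-12). That mean still contains the brightest probe set of each gene, and is the same value for genes with 1 probe set, such as DKK4 and SP5. The test therefore cannot exclude the choice of probe set, and the size of single rises may depend on it. Without averaging, the list did not pass with an estimated correlation (camera adjusted p = 0.271). An exchange of 1 array of each group is argued against by the gene-centred correlations, which were at least 0.551 between arrays of the same label and at most -0.738 between labels. Labels of the whole groups exchanged would turn every direction given here and stay open: 0 probe sets were named HOXA5, and values looked up from memory (see the processing summary) were not used to decide it. A true rise of these genes with HOXA5, or a response of the knock-down cells, stays open as well and was not tested, as there is no control group. For the same reason, a difference between the transduced cell populations that does not come from HOXA5 cannot be told apart.

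G2/M genes stood slightly lower in the overexpressing arrays (array medians differing by -0.14 ± 0.03, SE), though no member passed and the list did not pass with an estimated correlation (adjusted p = 0.50) or in fry (0.088). RNA integrity stays open: the 3' minus 5' values of ACTB and GAPDH differed between groups by -0.068 ± 0.070 and -0.024 ± 0.026 (SE), too wide a spread for ACTB to exclude a shift of that size. A lower share of dividing cells would lower G1/S genes as well, and their median difference was 9.3e-04, and its bootstrap interval over genes (-0.059 to 0.046) lies above -0.069, which is 0.5 of the G2/M median. Genes are not replicates, however, and over arrays the difference less 2 SE was -0.074, a condition added to the written rule, which alone would have excluded it, so this explanation stays open. The histone list stood higher, with 11 of 11 members above 0 (median 0.44), but it did not pass with an estimated correlation (camera adjusted p = 0.271). Whether these probe sets follow S phase was not tested, so the list cannot decide for or against fewer dividing cells.

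ETV5 (3.58 ± 0.12, SE) and SPRY2 (2.83 ± 0.11), both induced by ERK signalling, were among the large rises, which led to the hypothesis that ERK pathway output may be higher in the arrays labelled overexpressing. A list of 20 other ERK output genes was written before their test, but after large rises in these same 4 arrays had been seen. The list test is therefore not independent of those rises and adds no separate support. Of the 20 genes, 19 were measured, 12 rose and none fell, with a median of 0.69 (camera adjusted p = 3.20e-15 over 34 lists). With an estimated correlation the prediction, written for an unadjusted p, was met, but the adjusted p was 0.22. The rises included DUSP4 (2.02), DUSP6 (1.81), SPRED2 (1.81), ETV4 (1.70), PHLDA1 (1.30) and SPRY4 (0.76), while HBEGF (-0.05) and EREG (-0.02) did not pass; 4 of the 19 also stand in the fixed lists, whose tests had been seen by then. Higher ERK pathway output would go with these rises, but ERK activity was not measured here and the list test cannot decide it. The same open question on the labels applies to the direction of the rises.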
